A study of Mus musculus with 8 samples.

How the data were processed

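The libraries were RNA sequencing libraries of mouse distal convoluted tubule fragments, 4 from control animals and 4 from animals with a distal convoluted tubule-specific, tamoxifen-inducible deletion of floxed Cnb1 (gene symbol Ppp3r1, the regulatory B subunit of the phosphatase calcineurin). All animals carried a Cre recombinase transgene named for the NaCl cotransporter of this segment and a Tomato reporter, per the labels. Tamoxifen was given by mouth at 2 mg per animal and day for 5 days, and tubules were taken 3 weeks later. Each library came from 1000 tubule fragments collected on a large-particle flow sorter, per the labels' protocols. The group of each library was taken from the deposited genotype label, and each label named another animal number. Replicate numbers below only name libraries in the order of deposit.

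The files hold whole-number read counts per Ensembl mouse gene, as deposited by the authors, without normalization. Per the submitters' processing notes, bcl2fastq 2.20, fastp 0.20.0 and STAR 2.7.4a were used with the mouse build GRCm38.p6, and the step each tool served and its settings are not given in the sources used here. The counting program, the gene annotation release and the strand setting are not given in the sources used here. Without a strand setting, reads of genes that overlap on opposite strands cannot be told apart, and 38 of the 109 named genes have exons that overlap another gene, 15 of them with a partner that held over 10% as many counts. How reads that match several near-identical copies were counted is not given either, so values of genes with close copies, such as ribosomal protein genes, are uncertain. Gene names and coordinates come from GENCODE vM21 on GRCm38, in which 42347 of 42416 gene identifiers had a name. The other 69 held 0.0199% of all counts. Where several identifiers share a symbol (96 symbols), the one with most counts stands for it in the gene lists.

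Total counts ranged from 18161442 to 45150953 per library. Genes were kept by edgeR's filterByExpr, library sizes were scaled by TMM, and groups were compared with edgeR 4.0.16's two-sided quasi-likelihood F test (QL) under R 4.3.3, with genotype as the single factor and all 8 libraries in the fit. All adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Levels are CPM (counts scaled to a common library total) on TMM-scaled library sizes. Fold changes are KO over Control on the log2 scale, and their standard errors are approximate, taken as the fold change divided by the square root of the F statistic. With simulated counts for this comparison (14058 genes, 200 of them changed), the test recovered 14.9% of genes changed 1.5-fold, 64.2% of genes changed 2-fold and 100% of genes changed 4-fold, and 4.8% of its calls were unchanged genes. The changed genes were drawn only from genes with higher counts, and the simulated counts held no trend shared across genes within a library. The rates therefore do not extend to genes at low counts or to libraries with such a trend.

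The 29 gene lists, the named-gene rule, the tests and the alternative settings were fixed before the data were examined, except where stated. Of the lists, 28 could be tested, since the red blood cell list had too few measured members. Lists were tested with limma 3.58.1's camera on voom log2 CPM with a preset correlation of 0.01, and beside it with camera using a correlation estimated per list and with fry. Fry's directional test asks whether a list's genes move one way on balance and does not compare them with other genes. Members past the threshold are counted over all genes tested and also adjusted over the list alone. A per-library list level is the mean of log2(CPM + 1) over its members. Single values per library were compared by exact two-sided permutation tests over the 70 assignments of 8 libraries into 4 and 4, which cannot give a p below 0.0286. These tests were run in R, and the counting intervals and chi-square comparisons given below used Python 3.11.15 and SciPy 1.17.1.

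The rule for named genes took all calcineurin and NFAT list members, 12 genes set by name, the 15 highest and the 15 lowest fold changes among protein-coding or otherwise named genes past the threshold with a mean of at least 1 CPM in a group and no overlap between groups, and in each list up to 4 members with the smallest p past the threshold, or 2 if none passed. Predicted gene models were left out of the highest and lowest, and some genes that the rule took are not reported here. Intervals at 95% for genes with 1 to 3 counts in a group are exact intervals for a ratio of counts and, since reads are not independent molecules, cover counting error only.

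Alternatives to each result were DESeq2 1.42.0, upper-quartile scaling, library totals without scaling factors, no filter on low counts, a filter of at least 5 CPM in 4 libraries, limma-voom with library quality weights, removal of mitochondrially encoded genes, a batch term for the form of the file name, a block for the series of the animal number, a fold change of at least 1.5, and leaving out each library. The file names of Control replicate 2 and KO replicate 1 carry an index sequence and the others do not. Animal numbers fall into 3 series, which the labels do not explain. Alternatives without both Control replicate 1 and KO replicate 4, and with each library's trend with exon length and GC content removed, were chosen after seeing the data. No library was left out of the results. The 28 pairs of libraries were compared by chi-square of counts: within groups the statistic was 28.8 to 183 per degree of freedom, so no library was a repeat of another.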

Results

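RNA was sequenced from sorted fragments of the mouse distal convoluted tubule, the short nephron segment that reabsorbs NaCl through the thiazide-sensitive cotransporter and sets the final urinary magnesium. The 4 Control libraries and the 4 libraries labelled KO came from animals without and with the floxed Cnb1 allele, all given tamoxifen. The comparison addresses what loss of calcineurin in this segment does to its transcriptome, in a study of the kidney side effects of calcineurin inhibitor drugs. Total counts were 23190905, 42389558, 19911826 and 20493441 in Control replicates 1 to 4, and 45150953, 25230283, 25230884 and 18161442 in KO replicates 1 to 4. Between 18263 and 19470 genes had at least 1 count in a library. Transcripts encoded by the mitochondrial genome took 18.3% ± 0.967 of counts (SD, n = 4) in Control and 15.9% ± 2.10 (SD, n = 4) in KO, with an exact permutation p of 0.0857. Over the 500 most variable genes, the first principal component held 49.3% of the variance and placed the Control libraries between -23.8 and -12.0 and the KO-labelled libraries between -0.47 and 42.5. KO replicate 4 lay at the high end of it, and Control replicate 1 stood apart at 30.4 on the second component, which held 19.0%.

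The targeted gene, Ppp3r1 (ENSMUSG00000033953, chromosome 11, 17159263 to 17200375, plus strand, GRCm38), encodes the regulatory subunit of calcineurin. Its level was 108, 97.4, 99.8 and 84.4 CPM in Control replicates 1 to 4 and 80.7, 74.0, 97.7 and 92.5 CPM in KO replicates 1 to 4. The log2 fold change was -0.18 ± 0.13 (SE, n = 4 per group, edgeR QL adjusted p = 0.548), with an exact permutation p of 0.171, so the groups were not separated by it. Gene-level counts cover the whole gene, and the labels do not say which exons were floxed. Wdr92 overlaps Ppp3r1 on the same strand and held 27.6% as many counts, and reads of the shared part cannot be assigned. The target therefore does not check the genotype labels, and the libraries are called KO-labelled or KO by their deposited label alone.

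Genes of the calcineurin pathway itself did not pass the threshold. Of the 19 measured members of the calcineurin and NFAT list, 0 passed the threshold by edgeR QL, 0 had an unadjusted p under 0.05, and 0 passed by DESeq2 or limma-voom. The catalytic subunits Ppp3ca, Ppp3cb and Ppp3cc had log2 fold changes of 0.03 ± 0.11, -0.07 ± 0.11 and -0.06 ± 0.13 (SE), and those of the latter pair turned positive with library totals as the scaling. Rcan1, a feedback inhibitor of calcineurin and a target of NFAT, stood at 69.8 ± 31.0 CPM in Control and 49.1 ± 3.95 CPM in KO (SD, n = 4 each), a log2 fold change of -0.51 ± 0.25 (SE). Without Control replicate 2, which stood at 116 CPM against 51.8 to 58.4 CPM in the other Control libraries, it was -0.15. The transcription factors Nfatc1, Nfatc2, Nfatc3, Nfatc4 and Nfat5 had log2 fold changes of 0.39, 0.09, 0.14, -0.58 and 0.33. The regulators Rcan2, Rcan3, Cabin1 and Akap5 had -0.25, 0.15, 0.34 and -0.09, the last of these turning positive with library totals. The kinases Dyrk1a and Gsk3b had 0.19 and 0.16, and the CREB coactivators Crtc1, Crtc2 and Crtc3 had 0.21, 0.04 and 0.01. Ppp3r2, the testis form of the B subunit, had too few counts to be tested. The list as a whole did not pass camera (adjusted p = 0.384).

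Across the transcriptome, 191 genes were higher and 125 lower in KO, of 14268 tested by edgeR QL. The lower genes included the calcium-binding proteins Pvalb and Calb1, the vitamin D-inactivating enzyme Cyp24a1, the matrix genes Adamtsl3 and Loxl2, the urocanate-degrading enzyme Uroc1 and the insulin-like growth factor-binding protein Igfbp1. The higher genes included the calcium-binding protein S100a6, the membrane proteins Psca and Gpnmb, the annexin Anxa2, the intermediate filament gene Nefm, and genes of mitosis such as Bub1, Kif18b and Cdkn3. By 2-fold or more, 137 were higher and 87 lower, and protein-coding genes made up 186 of the higher and 116 of the lower genes. In all 316 genes the 4 KO libraries did not overlap the 4 Control libraries. Such separation was seen in 1347 genes, or 9.44% of those tested, where chance alone gives 2.86%, and 1989 genes had an unadjusted p under 0.05. The count varied with the library left out: it was 198, 166, 111 and 53 without Control replicates 1 to 4 in turn, and 175, 36, 388 and 110 without KO replicates 1 to 4. Each of these fits has 1 library fewer, and the loss of power was not separated from reliance on a given library. It was 199 with a batch term for the form of the file name and 29 with a block for the series of the animal number, and with library totals as the scaling, which moved the median of all genes from -0.02 to 0.13, 72.9% rather than 60.4% of calls were higher.

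**Figure D1:**
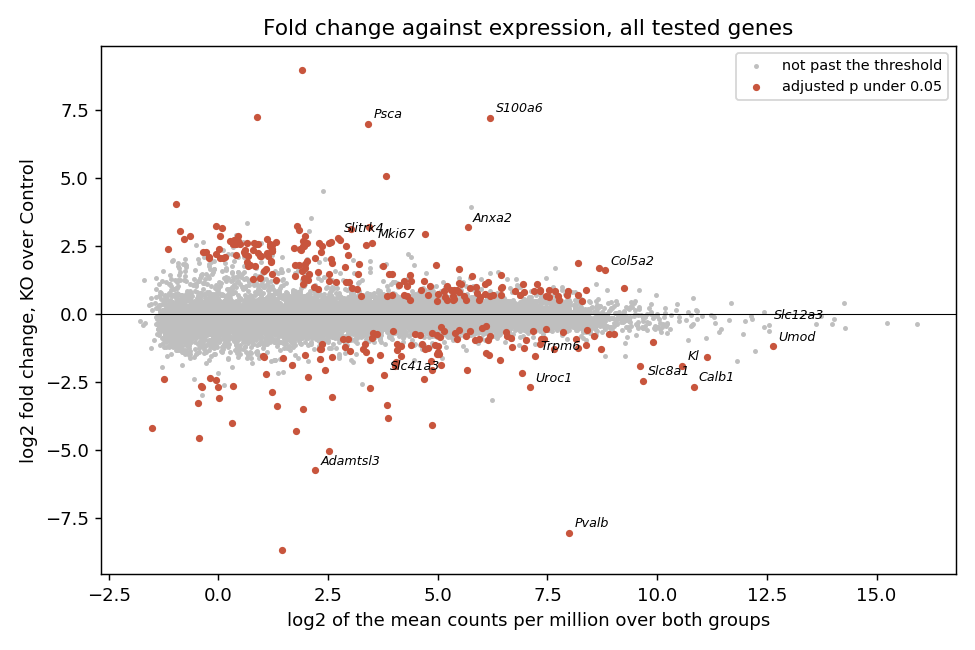
Log2 fold change (KO over Control) of each of the 14268 tested genes against the log2 of its mean CPM over both groups, with genes at an edgeR QL adjusted p under 0.05 in red. Pvalb, at -8.06, lies far below the other lower genes of its expression level, and Slc12a3, at -0.41, lies among genes that did not pass.

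Among the 15 lowest genes, Adamtsl3 fell from 8.99 ± 3.40 to 0.167 ± 0.0584 CPM, with a log2 fold change of -5.76 ± 0.37 (edgeR QL adjusted p = 0.000366). Uroc1 fell from 237 ± 37.9 to 36.5 ± 15.5 CPM (log2 -2.70 ± 0.29). Asb11, a substrate adaptor of ubiquitin ligases, fell by 3.37 on the log2 scale, and Htra4, a serine protease, fell by 5.05. Igfbp1 (-4.02), Cpne7 (-3.51), Kcns1 (-3.40), Rtn1 (-3.28), Lgi3 (-2.68) and the noncoding host gene Mir670hg (-4.33) fell too. Over the planned settings that tested them, Cpne7 lay between -3.80 and -2.81 and Kcns1 between -4.05 and -2.99. Colq had 453 counts over the Control libraries and 1 over the KO libraries, a scaled ratio of 537 with a 95% counting interval of 95.9 to 21259. The ratio was 319 without KO replicate 1, 833 without Control replicate 2 and 282 without Control replicate 4, which held 262 of the counts. Its exons overlap those of a predicted gene on the same strand with more counts.

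Among the 15 highest genes, Slitrk4, a neuronal transmembrane protein, rose from 1.63 ± 0.420 to 11.7 ± 2.99 CPM (log2 2.81 ± 0.26, edgeR QL adjusted p = 0.00172). Nefm, which overlaps its neighbour Nefl on the opposite strand, rose from 1.68 ± 0.326 to 14.5 ± 6.52 CPM (log2 3.11 ± 0.36, adjusted p = 0.00505). S100a6 (log2 7.22 ± 1.39) and Psca (7.0 ± 1.16) rose from under 1 CPM in Control on average to 146 ± 220 and 21.1 ± 21.5 CPM in KO, with SDs as large as the means. S100a6 stood at 24.7, 81.3, 4.53 and 472 CPM in KO replicates 1 to 4. Samd5 (5.09), the complement protease C1s1 (3.21), the chloride channel Best2 (2.85), the cytoskeletal linker Gas2l3 (2.85), the kinetochore protein Nsl1 (2.77), Kif18b (3.24) and Cdkn3 (3.15) rose as well. Gpnmb had 670 counts in KO against 1 in Control, a scaled ratio of 565 with a 95% counting interval of 101 to 22354, and the prostaglandin D receptor gene Ptgdr had 343 against 2, a ratio of 145 with an interval of 39.7 to 1199. KO replicate 4 held 445 of the Gpnmb and 214 of the Ptgdr counts, and without it the ratios were 228 and 65.3. That of Gpnmb was 851 without KO replicate 1 and 333 without Control replicate 2. Without KO replicate 4 the log2 fold change of S100a6 was 5.23 and that of Psca 6.19, of Samd5 4.18 and of Gas2l3 2.23. Without Control replicate 2 that of Samd5 was 6.01 and that of Best2 3.68. Over the planned settings that tested them, S100a6 lay between 5.23 and 7.61 and Psca between 6.19 and 7.89. Of the 47 named genes past the threshold, 8 kept their call under all 17 other settings that were fixed in advance: Adamtsl3, Asb11, Cnnm2, Mki67, Nefm, Pvalb, Slitrk4 and Uroc1. Without KO replicate 2 the call was lost for 36 of the 47, and without Control replicate 4 for 30.

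Some genes of magnesium transport fell in the KO-labelled libraries. Parvalbumin (Pvalb, ENSMUSG00000005716, chromosome 15, 78191114 to 78206400, minus strand), the cytosolic calcium-binding protein that marks the early distal convoluted tubule, fell from 508 ± 344 to 1.88 ± 0.305 CPM (SD, n = 4 each), a log2 fold change of -8.06 ± 0.56 (SE, edgeR QL adjusted p = 0.000375). It was between 1.5 and 2.14 CPM in all 4 KO libraries. Trpm6 (chromosome 19, 18749983 to 18892511, plus strand), the apical magnesium channel, fell from 221 ± 42.1 to 76.3 ± 25.8 CPM (log2 -1.53 ± 0.24, adjusted p = 0.0156). Cnnm2 (chromosome 19, 46761596 to 46880192, plus strand), a basolateral protein of magnesium handling, fell from 143 ± 28.6 to 62.1 ± 6.31 CPM (log2 -1.21 ± 0.15, adjusted p = 0.00874). Slc41a3 (chromosome 6, 90604725 to 90646412, plus strand), a magnesium transporter, fell from 22.8 ± 9.65 to 4.72 ± 0.289 CPM (log2 -2.27 ± 0.31, adjusted p = 0.00988). The related channel Trpm7 rose, with a log2 fold change of 0.95 ± 0.15 (adjusted p = 0.0157).

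Of the 17 measured members of the magnesium list, 1 rose (Trpm7), 5 fell (the above and Arl15, at -1.74) and 11 did not pass, and adjusted over the list alone 1 rose and 6 fell. Egf, whose product stimulates Trpm6, was at 6943 ± 1006 CPM in Control and 2702 ± 1216 in KO, a log2 fold change of -1.36 ± 0.31 that missed the threshold (edgeR QL adjusted p = 0.0552) and passed it by DESeq2 and limma-voom. The list's mean log2 fold change was -0.89, pulled down by the calcium-binding protein Pvalb at -8.06. Its median was -0.10, which became 0.05 with library totals as the scaling. Camera placed the list lower (adjusted p = 0.00306), which was not kept with an estimated correlation (adjusted p = 0.195 with an estimated correlation), and fry's adjusted p was 0.00384. Without KO replicate 2 the list held 0 higher and 2 lower calls, and without Control replicate 4 it held 0 and 3. With a block for the series of the animal number it held 0 and 2. Trpm6 and Slc41a3 lost their calls without KO replicate 2 (adjusted p = 0.059 and 0.054), and Trpm6 also without Control replicate 4 (adjusted p = 0.06). Both also lost them with the block (adjusted p = 0.089 and 0.0578), with log2 fold changes of -1.41 and -1.99.

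**Figure D2:**
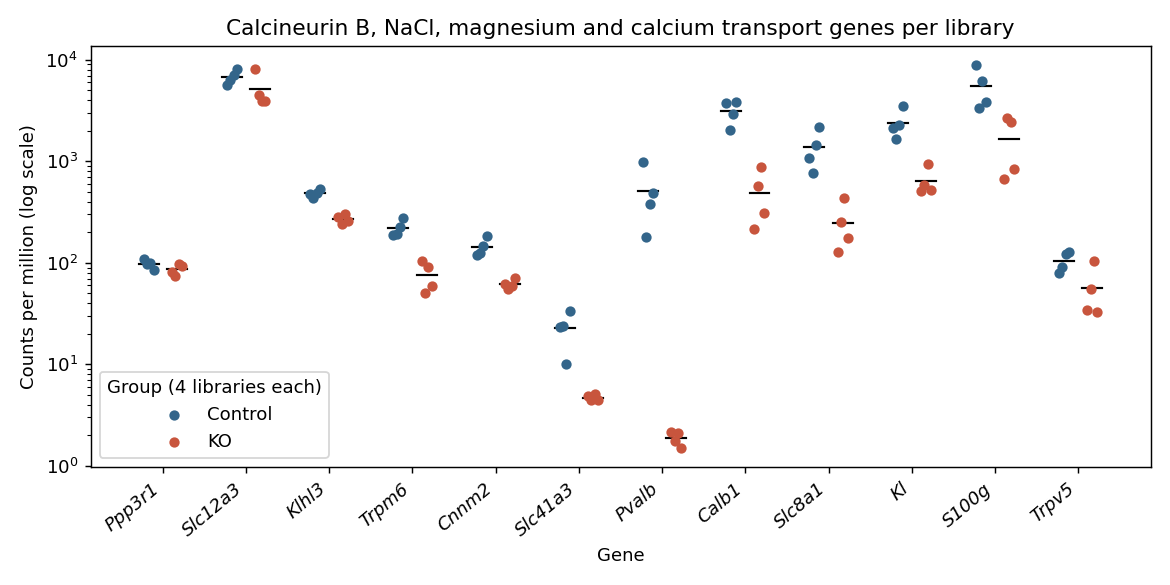
CPM on a log scale of Ppp3r1 and of 11 genes of NaCl, magnesium and calcium transport, with 1 point per library (4 Control, 4 KO) and a black line at each group's mean. Ppp3r1 and Slc12a3 overlap between the groups, and the 4 KO libraries of Pvalb lie between 1.5 and 2.14 CPM.

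Some genes of calcium transport and of the vitamin D and klotho axis fell as well. Calb1 (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064, plus strand), the calbindin that ferries calcium through the cell, fell from 3147 ± 859 to 491 ± 295 CPM (log2 -2.68 ± 0.42, edgeR QL adjusted p = 0.0155). Slc8a1 (chromosome 17, 81373105 to 81738377, minus strand), the basolateral sodium-calcium exchanger, fell from 1376 ± 614 to 250 ± 136 CPM (log2 -2.46 ± 0.42, adjusted p = 0.0208). Kl (chromosome 5, 150952607 to 150993817, plus strand), which encodes the FGF23 coreceptor klotho, fell from 2405 ± 793 to 640.5 ± 198 CPM (log2 -1.91 ± 0.27, adjusted p = 0.0129). Cyp24a1, which overlaps Pfdn4 on the opposite strand, fell from 19.2 ± 9.61 to 2.87 ± 1.51 CPM (log2 -2.72 ± 0.44, adjusted p = 0.017). S100g, a small cytosolic calcium-binding protein, had a log2 fold change of -1.75 ± 0.49 (adjusted p = 0.125), and the apical calcium channel Trpv5 had -0.89 ± 0.35 (adjusted p = 0.286).

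Of the 14 measured calcium list members, 0 rose, 4 fell and 10 did not pass by edgeR QL over all genes, and adjusted over the list alone 2 rose and 9 fell. At an unadjusted p under 0.05, 2 were higher and 9 lower. DESeq2 called 1 higher and 7 lower, and limma-voom 1 higher and 5 lower. Camera placed the list lower (adjusted p = 0.000106, mean log2 fold change -0.92, median -0.70), with an adjusted p of 0.383 with an estimated correlation and 0.0453 by fry. Calls numbered 0 without KO replicate 2, 1 lower without Control replicate 4 and 0 with a block for the series of the animal number. Of the 4 genes, Kl lost its call without KO replicate 2 and with the block, Calb1 and Cyp24a1 also without Control replicate 4, and Slc8a1 also without Control replicate 3 or 4 and KO replicate 4 (adjusted p from 0.0579 to 0.097). With the block the log2 fold changes of Calb1, Cyp24a1, Slc8a1 and Kl were -2.68, -2.72, -2.28 and -1.69.

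The list of distal convoluted tubule identity genes held 1 member that rose (the transcription factor Tfap2b, 0.63 ± 0.12), 5 that fell (Pvalb, Kl, Klhl3, Calb1 and Trpm6) and 9 that did not pass, of 15 measured, and adjusted over the list alone 1 rose and 8 fell. Of the 15, 9 also belong to another list, among them all 5 that fell. The fall is therefore not separate from that of the magnesium, calcium and NaCl genes. Members in no other list went both ways: Tfap2b 0.63, Slc16a7 -0.49, Erbb4 0.42, Sall3 0.17, Abca13 0.15 and Emx1 -0.11. Camera placed it lower (adjusted p = 0.000112, mean -1.09, median -0.49), with an adjusted p of 0.195 with an estimated correlation and 0.00384 by fry. Pvalb, at -8.06, pulls down this mean as well. Its per-library level was 9.45 ± 0.135 in Control and 8.40 ± 0.137 in KO (mean log2(CPM + 1), SD, n = 4 each, exact permutation p = 0.0286, 0.166 after adjustment over the lists). Lower calls fell to 1 without KO replicate 2 and to 2 without Control replicate 4, and to 1 with a block for the series of the animal number.

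The NaCl cotransporter itself did not pass. Slc12a3 (ENSMUSG00000031766, chromosome 8, 94329201 to 94366214, plus strand) was at 6783 ± 1045 CPM in Control and 5120.1 ± 1988 in KO (SD, n = 4 each), a log2 fold change of -0.41 ± 0.25 (SE, edgeR QL adjusted p = 0.49), and KO replicate 1 stood at 8074 against 3911 to 4521 CPM in the other KO libraries. Klhl3, the adaptor that marks WNK kinases for degradation, fell from 484 ± 41.4 to 273 ± 27.8 CPM (log2 -0.83 ± 0.12, adjusted p = 0.0142), and its substrate kinase Wnk4 fell from 646 ± 106 to 387 ± 58.8 CPM (log2 -0.74 ± 0.16, adjusted p = 0.0482). Of the 24 measured members of the NaCl and WNK list, 0 rose, 2 fell and 22 did not pass, and adjusted over the list alone 1 rose and 4 fell. At an unadjusted p under 0.05, 3 were higher and 4 lower, DESeq2 called 1 and 4, and limma-voom 1 and 3. The list did not pass camera (adjusted p = 0.612, mean -0.07 and median -0.04, both positive with library totals) and had an adjusted p of 0.0453 by fry. Wnk4 lost its call without any 1 of the 8 libraries, with library totals as the scaling, with a filter of at least 5 CPM, with a batch term for the form of the file name and with a block for the series of the animal number, with adjusted p-values from 0.0565 to 0.181. Klhl3 lost it without Control replicate 4, without KO replicate 2 and with the block (adjusted p = 0.055, 0.059 and 0.0905).

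Most measured genes of the cell cycle list rose in the KO-labelled libraries, from low levels. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand), a nuclear protein of dividing cells, rose from 3.22 ± 0.879 to 19.6 ± 8.60 CPM (SD, n = 4 each), a log2 fold change of 2.60 ± 0.34 (SE, edgeR QL adjusted p = 0.00988). The mitotic topoisomerase Top2a (chromosome 11, 98992943 to 99024189, minus strand) rose from 3.03 ± 0.542 to 17.7 ± 8.30 CPM (log2 2.54 ± 0.35, adjusted p = 0.0102). Cyclin A2 (Ccna2), which overlaps Exosc9 on the opposite strand, rose from 1.59 ± 0.483 to 9.81 ± 5.11 CPM (log2 2.62 ± 0.40, adjusted p = 0.0142), and the replication licensing factor Mcm6 from 11.3 ± 1.34 to 26.4 ± 6.13 CPM (log2 1.23 ± 0.18, adjusted p = 0.0142). Of the 20 measured members 15 rose, 0 fell and 5 did not pass (adjusted over the list alone, 18 rose and 0 fell). At an unadjusted p under 0.05, 0 were lower, and DESeq2 and limma-voom called 0 lower. Among the 5, Pcna had 0.22 and Ccnd1 0.04.

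The cell cycle list had a mean log2 fold change of 1.77 and a median of 2.27, and camera placed it higher (adjusted p = 2.70e-17), with an adjusted p of 0.231 with an estimated correlation and 0.0246 by fry. Its per-library level was 2.15 ± 0.0432 in Control and 3.13, 3.48, 2.85 and 3.89 in KO replicates 1 to 4 (mean log2(CPM + 1), n = 4 each, exact permutation p = 0.0286, 0.166 after adjustment over the lists). Of the 10 measured immune markers, Csf1r, which overlaps Hmgxb3 on the opposite strand with 149% as many counts, and Cd68 had log2 fold changes of 2.21 ± 0.52 and 1.96 ± 0.54 that missed the threshold (edgeR QL adjusted p = 0.064 and 0.116) and passed it without KO replicate 3 (0.0314 and 0.0483). Csf1r stood at 72.2 CPM in KO replicate 1, without which its log2 fold change was 1.44. Fcer1g (-1.27), H2-Ab1 (-0.90) and Cd74 (-0.73) went the other way, and the level of the immune list differed by 0.07 between groups (mean log2(CPM + 1), exact permutation p = 0.714). As a share of all counts the immune list was higher in KO, at 0.00594% against 0.00313% (exact permutation p = 0.0286, 0.104 after adjustment over the lists). The 15 calls became 8, 7, 5 and 2 without Control replicates 1 to 4 in turn and 10, 2, 14 and 7 without KO replicates 1 to 4, and 5 with a filter of at least 5 CPM. With a block for the series of the animal number the list held 1 call, with the list's mean at 1.77. Ccna2 and Mcm6 lost their calls without Control replicate 4, without KO replicate 2 and with the block, Top2a with the block alone, and Mki67 in none of the 17 settings. The mean stayed between 1.51 (without KO replicate 4) and 1.92 (without KO replicate 3) when single libraries were left out.

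**Figure D3:**
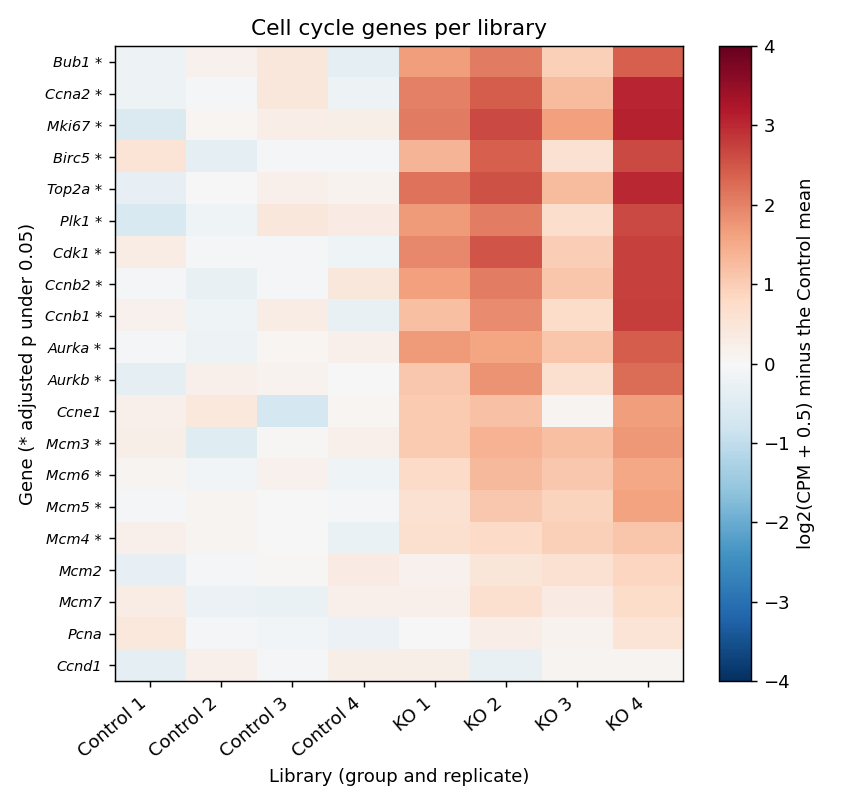
Level of the 20 measured cell cycle genes in each library, as log2(CPM + 0.5) minus the mean of the 4 Control libraries (color scale from -4 to 4), with genes at an edgeR QL adjusted p under 0.05 marked by a star. The genes that passed are above the Control mean in all 4 KO libraries, with the strongest color in KO replicate 4, and Pcna and Ccnd1 show little color.

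Of genes tied to injury, matrix and early response, few members passed. In the injury list 1 of 16 measured members rose, Anxa2, from 10.1 ± 3.57 to 92.6 ± 60.8 CPM (log2 3.19 ± 0.49, edgeR QL adjusted p = 0.0148), 0 fell and 15 did not pass. Adjusted over the list alone, 3 rose and 1 fell. At an unadjusted p under 0.05, 9 were higher and 1 lower, DESeq2 called 2 higher and 1 lower, and limma-voom 3 and 0. Camera placed the list higher (adjusted p = 0.0181; 0.481 with an estimated correlation). In the fibrosis and TGF-beta list the activator of latent TGF-beta Thbs1 (0.88 ± 0.18, adjusted p = 0.041) and the integrin subunit Itgb6 (0.70 ± 0.15, adjusted p = 0.049) rose, while the matricellular gene Ccn2 (-1.32 ± 0.24, adjusted p = 0.0248) and the collagen crosslinking enzyme Loxl2 (-3.05 ± 0.45, adjusted p = 0.0142) fell, and 10 of 14 did not pass. Adjusted over the list alone 9 rose and 2 fell, and camera placed it higher (adjusted p = 0.00559; 0.481 with an estimated correlation). Of 22 measured immediate early and heat shock genes, Fosb rose (1.76 ± 0.27, adjusted p = 0.0142), Ier3 fell (-2.17 ± 0.47, adjusted p = 0.049) and 20 did not pass, with 4 and 1 adjusted over the list alone. That list was drawn up as genes induced by tissue dissociation, and a response to tubule preparation was not told apart from one in the animals. Camera placed that list higher (adjusted p = 0.0151; 0.687 with an estimated correlation), while its mean was 0.15 and its median 0.09. The camera calls of the injury and immediate early lists were lost without Control replicate 1 (adjusted p = 0.0771 and 0.0798) and without Control replicate 3 (0.0503 and 0.115), and that of the immediate early list without Control replicate 4 (0.144), with its mean at -0.03 and -0.02 in the latter pair of fits. Leaving out 1 library ended the call of Thbs1 in 8 of 8 fits, of Itgb6 and Ier3 in 7, of Ccn2 in 6, of Anxa2 in 2 (Control replicate 4, KO replicate 2), of Loxl2 in 1 (KO replicate 2) and of Fosb in 1 (Control replicate 4). Without Control replicate 2, which stood at 413 CPM against 99.3 to 183 CPM in the other Control libraries, the log2 fold change of Ier3 was -1.52. With a block for the series of the animal number the calls of all 7 genes were lost (adjusted p from 0.0578 to 0.189), and with a batch term for the form of the file name or a filter of at least 5 CPM those of Thbs1, Itgb6 and Ier3. With library totals as the scaling none of the 3 lists passed.

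**Figure D4:**
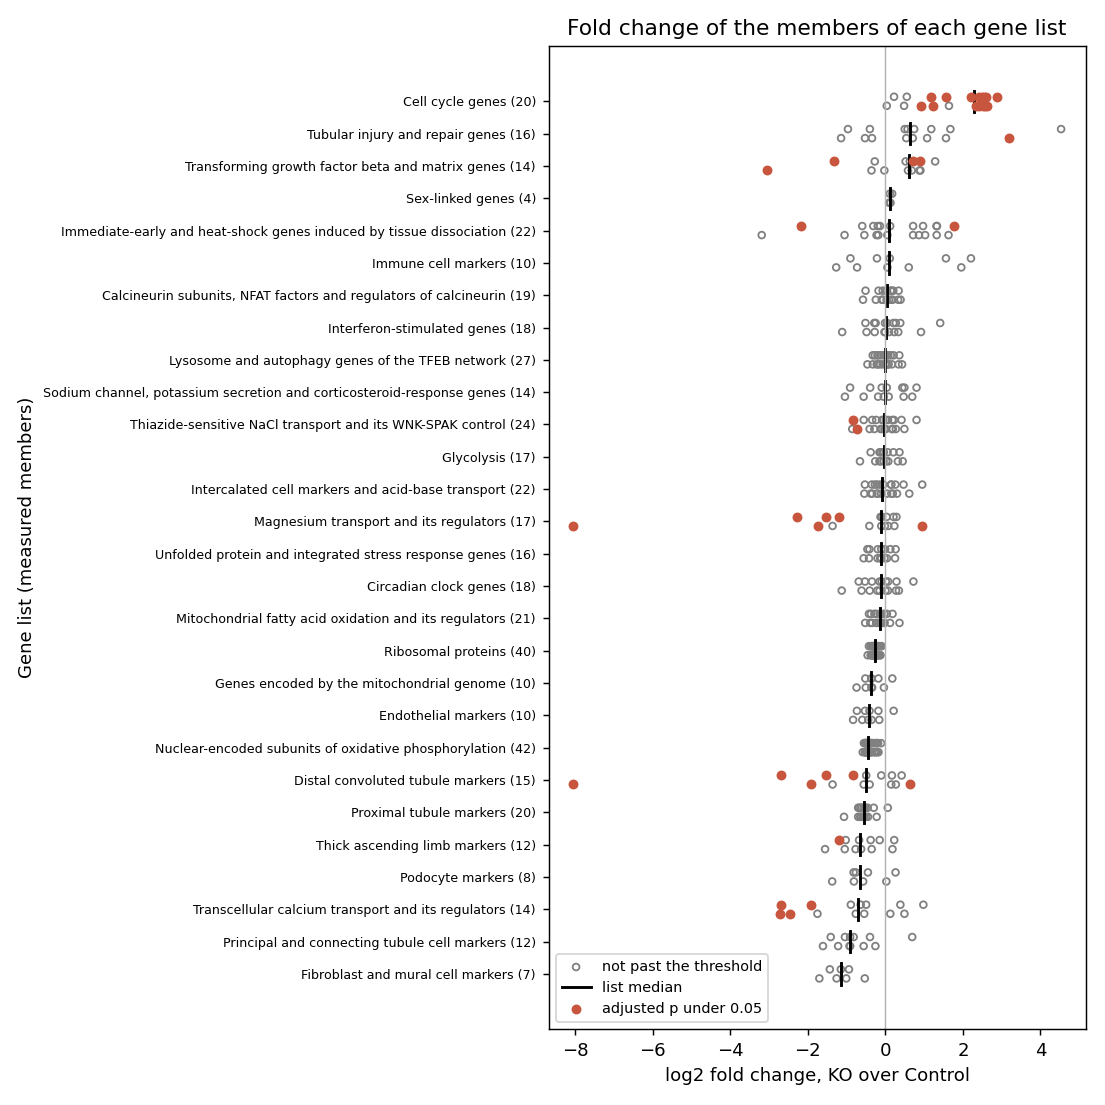
Log2 fold change (KO over Control) of each measured member of the 28 tested gene lists, ordered by median, with members at an edgeR QL adjusted p under 0.05 filled in red, other members open and a black bar at the list median. Cell cycle genes form the list with the highest median, 2.27, and Pvalb stands at -8.06 in the magnesium and identity lists.

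Markers of other cell types that the sorted fragments could hold showed few single-gene calls. Umod, the abundant thick ascending limb glycoprotein, fell from 8812 ± 2056 to 3859 ± 978 CPM (log2 -1.19 ± 0.25, edgeR QL adjusted p = 0.041), the only call among 12 measured thick limb genes, with 0 rising by any of the 3 tools and 2 lower adjusted over the list alone. Camera placed the list lower (adjusted p = 0.00111; 0.481 with an estimated correlation), and Umod lost its call without Control replicate 1, 3 or 4, without KO replicate 1, 2 or 4, with a filter of at least 5 CPM, with the file-name batch term and with the animal-number block (adjusted p from 0.0536 to 0.158). Of 12 principal cell genes 0 passed, with Tfcp2l1 at 0.69 ± 0.18 and Avpr2, which overlaps Arhgap4, at -0.92 ± 0.24. Adjusted over the list alone, 1 rose and 5 fell, and camera placed the list lower (adjusted p = 0.000174; 0.383 with an estimated correlation). At an unadjusted p under 0.05, 1 was higher and 7 lower, DESeq2 called 1 and 3, and limma-voom 1 and 2. Of 20 proximal tubule genes 0 passed, also adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2 and limma-voom, with Fbp1 at -0.68 ± 0.34. Camera placed that list lower (adjusted p = 0.00306; 0.687 with an estimated correlation), a call lost without Control replicate 2 or 3 or KO replicate 4 (0.139, 0.0749 and 0.164). Of 22 intercalated cell genes 0 passed and 0 adjusted over the list alone, with Atp6v1b1 at 0.47 ± 0.13, Oxgr1 at 0.62 ± 0.18 and Slc26a4, which encodes pendrin, at -0.14 ± 0.24. Of these, 5 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 1, and camera's adjusted p was 0.936.

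Among non-epithelial markers, 0 of 10 endothelial genes passed (Esam -0.73 ± 0.38, Pecam1 -0.83 ± 0.39), and 0 had an unadjusted p under 0.05 or were called by DESeq2 or limma-voom. Camera placed them lower (adjusted p = 0.0274; 0.687 with an estimated correlation), a call lost without Control replicate 2, 3 or 4 or KO replicate 1 or 4 (adjusted p from 0.0627 to 0.178). Of 7 stromal genes 0 passed by edgeR QL, 2 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 1 each. They included Acta2 at -1.70 ± 0.52, Tagln, which overlaps Pcsk7, at -1.43 ± 0.52 and renin (Ren1) at -1.26 ± 0.69, and camera placed them lower (adjusted p = 0.00249; 0.481 with an estimated correlation). The 8 podocyte genes held 0 calls and 0 unadjusted p-values under 0.05 with any of the 3 tools (Wt1 -1.37 ± 1.00; camera adjusted p = 0.689). Of 10 immune genes 0 passed by edgeR QL or limma-voom, 5 had an unadjusted p under 0.05, DESeq2 called 3 higher, and 3 rose and 1 fell adjusted over the list alone. Their mean was 0.34 and their median 0.08, while camera's sign was down (adjusted p = 0.846). By per-library level, 1 of 10 cell type lists, the identity list, had an exact permutation p under 0.05 (n = 4 per group).

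Genes of the respiratory chain and of the ribosome were lower on average without a single-gene call. Of 42 nuclear oxidative phosphorylation genes 0 had a fold change above 0 and 0 passed by edgeR QL, DESeq2 or limma-voom, with 10 lower at an unadjusted p under 0.05. An example is Ndufb10 at -0.53 ± 0.20. Of 40 ribosomal protein genes 0 had a fold change above 0 and 0 passed with any of the 3 tools, with 1 at an unadjusted p under 0.05, and Rps2 stood at -0.42 ± 0.19 and Rpl7a at -0.38 ± 0.19. Camera placed both lists lower (adjusted p = 1.62e-09 and 0.000109), with adjusted p-values of 0.627 and 0.687 with an estimated correlation. In Control replicate 1 the level of both lists stood above all other libraries, at 9.83 and 8.23 against 8.97 to 9.06 and 7.41 to 7.5 in the other Control libraries (mean log2(CPM + 1)), and without it the ribosomal list's call was lost (adjusted p = 0.458, mean log2 fold change -0.03 against -0.27 with all libraries), while the oxidative phosphorylation list passed (adjusted p = 2.98e-05, mean -0.15 against -0.40). Of 10 mitochondrially encoded genes 0 passed by edgeR QL or limma-voom and DESeq2 called 1 lower, with mt-Nd1 at -0.51 ± 0.19 and mt-Nd2 at -0.36 ± 0.17 (camera adjusted p = 0.00306; 0.481 with an estimated correlation). Of 21 fatty acid oxidation genes 0 passed with any of the 3 tools and 3 had an unadjusted p under 0.05, with Etfb at -0.52 ± 0.21 and Esrrb at -0.42 ± 0.18. Camera placed that list lower (adjusted p = 0.0284; 0.687 with an estimated correlation), and its mean, -0.14, became 0.01 with library totals, where the call was lost, as it was without Control replicate 1, 2 or 3 or KO replicate 2 or 4 (adjusted p from 0.0503 to 0.164).

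The remaining 7 lists held no call by edgeR QL and did not pass camera. In the potassium and aldosterone list (14 measured) 2 rose and 2 fell adjusted over the list alone, with 6 at an unadjusted p under 0.05, and the mineralocorticoid receptor gene Nr3c2 stood at 0.47 ± 0.14 and the sodium channel subunit Scnn1a at 0.49 ± 0.14 (camera adjusted p = 0.917, with its sign up while mean and median were -0.01 and 0.00). DESeq2 and limma-voom each called 1 higher and 2 lower there. Interferon genes (18 measured; camera adjusted p = 0.917, sign down with a mean of 0.05) had 1 higher and 1 lower adjusted over the list alone and by DESeq2, 0 by limma-voom and 4 at an unadjusted p under 0.05, with Cxcl10 at 1.41 ± 0.37 and Usp18 at -1.11 ± 0.30. Circadian genes (18 measured, 0.39) had 1 lower adjusted over the list alone, by DESeq2, by limma-voom and at an unadjusted p under 0.05, with Nfil3 at -1.13 ± 0.27. Endoplasmic reticulum stress genes (16 measured, 0.284) had 1 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom, and passed camera without KO replicate 4 (adjusted p = 0.0363), with Herpud1 at -0.56 ± 0.17 and Sesn2 at 0.26 ± 0.14. Glycolysis genes (17 measured, 0.989) had 1 at an unadjusted p under 0.05, also called by DESeq2 and limma-voom, with Pfkp at 0.45 ± 0.12 and Aldoc at -0.65 ± 0.30. Lysosome genes (27 measured, 0.712) had 2 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, with Atp6v0d1 at -0.33 ± 0.11. The 4 sex-linked genes (0.384) had 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, with the Y-linked Kdm5d and Eif2s3y at 0.18 ± 0.15 and 0.13 ± 0.17. In all, camera with the preset correlation placed 16 of 28 lists past the threshold (4 higher, 12 lower), camera with an estimated correlation 0 (3 had an unadjusted p under 0.05) and fry 5.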

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

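The tests that left out Control replicate 1 were chosen only after the result was seen, and the test with length and GC trends removed was added after seeing the data, with its expected outcome written before its result. Each value in this part is a library that stood apart from the other 3 of its group, by a gap to its nearest neighbour that passed Dixon's 95% limit for 4 values. Of 274 groups of 4 values examined, for genes reported here, lists and quality measures, 22 held such a library, where chance at 1 in 20 gives 13.7, and 8 of the 22 were in Control replicate 1 and 6 in Control replicate 2.

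In Control replicate 1, the mean log2(CPM + 1) of the oxidative phosphorylation list was 9.83 and that of the ribosomal protein list 8.23, both above the rest of the group. The mean log2 fold change of the ribosomal protein list was -0.27 with all libraries (between-library SE 0.21) and -0.0289 without Control replicate 1 (SE 0.0865), the value predicted if that library alone carried the pattern. That of the oxidative phosphorylation list was -0.40 (SE 0.21) and -0.154 without Control replicate 1 (SE 0.0646), which lies between the values predicted with and without that explanation and leaves it open for these genes. With each library's trend of level with exon length and GC content removed, the mean over both lists went from -0.33 (SE 0.21) to -0.21 (SE 0.13). That value just passed the limit written beforehand for a pattern not carried by such a trend, but by less than its SE. It therefore does not decide whether such a trend carries the pattern. The 2 explanations cannot be told apart here because Control replicate 1 also held the strongest trend. Across genes, which are not independent replicates, Spearman's correlation of a library's deviation with exon length was -0.45 in Control replicate 1 and -0.08 to 0.25 in the others. The lower level of the ribosomal protein genes in KO may therefore come from 1 Control library rich in short transcripts, and for the oxidative phosphorylation genes an effect of the genotype beyond that library stays open.

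The other values of Control replicate 1 were Aldoc at 38.7 CPM, Etfb at 500.2 CPM, Mir670hg at 13.02 CPM and Rpl7a at 659 CPM, each highest in its group, and Nfatc1 at 4.24 CPM and the endothelial list at 2.02 (mean log2(CPM + 1)), each lowest. In Control replicate 2, Acta2 stood highest at 5.32 CPM, Rcan1 at 116 CPM, Sesn2 at 48.7 CPM, the injury list at 3.60 (mean log2(CPM + 1)) and the total count at 42.4 M counts. Ptgdr stood at 0.048 CPM in Control replicate 2 and Gpnmb at 0.052 CPM in Control replicate 3, against 0 in the other Control libraries, so these rest on 1 or 2 counts. Adamtsl3 was highest in Control replicate 4, at 14.04 CPM.

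Slc12a3 stood at 8074 CPM in KO replicate 1, against 3911 to 4521 CPM in the other KO libraries. In KO replicate 2, Rpl7a was highest at 396 CPM. In KO replicate 3, Colq held the group's single count, at 0.039 CPM. In KO replicate 4, S100a6 was highest at 472 CPM against 4.53 to 81.3 CPM in the others, Ptgdr was highest at 10.7 CPM, and Esam was lowest at 0.601 CPM.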

How the results depend on the processing

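The fits without both Control replicate 1 and KO replicate 4 and with length and GC trends removed were chosen only after the result was seen. No paired analysis was possible because the labels name no pairs of animals, and a block for the series of the animal number was fitted instead. The magnesium, calcium, identity and cell cycle lists kept camera's direction and their side of camera's threshold with the preset correlation under all planned and added settings. With an estimated correlation their adjusted p-values were 0.195, 0.383, 0.195 and 0.231, and 0 of 28 lists passed, against 16 with the preset value and 5 by fry. Ppp3r1 stayed short of the threshold throughout, with a log2 fold change between -0.25 and -0.02. Of the 316 changed genes (191 higher, 125 lower), DESeq2 called all among its 749 (422, 327), and limma-voom with quality weights called 519 (286, 233) with 290 of the 316. A filter of at least 5 CPM left 140 (62, 78; 44.3% higher), with fewer genes tested. A file-name batch term left 199 (105, 94) and the animal-number block 29 (5, 24; 17.2% higher). By construction, that block takes out Control replicate 4, the only library of its series. The pair of libraries left out together gave 109 (50, 59). Leaving out 1 library gave 36 to 388 changed genes, 15 to 257 higher and 21 to 131 lower, and 1 to 2 cell type lists with an exact p under 0.05, with fewer samples in each fit. That count of lists was 1 with all libraries, 2 with upper-quartile scaling and with no filter, and 3 as a percent of counts. Without the pair, 3 against 3 libraries cannot give an exact p under 0.05. The cause of the other differences was not tested. No named gene past the threshold changed sign under a planned setting. At this depth and n, simulated 1.5-fold changes were mostly missed, so genes that did not pass are not shown to be unchanged.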

Other observations

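The genes of the next paragraph and the tests on immune cells, KO replicate 4, the share of distal convoluted tubule cells, a shift of segment and fewer late-segment cells were chosen only after the result was seen.

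Some genes outside the fixed lists that passed by edgeR QL, picked by hand and not tested as groups, are given here. The Wnt receptor gene Fzd8 was higher in KO (21.6 ± 4.40 to 68.4 ± 20.7 CPM, SD, n = 4 each, log2 fold change 1.66 ± 0.22), and Sfrp1, a secreted antagonist of Wnt, was lower (1228 ± 242 to 328 ± 88.0 CPM, -1.91 ± 0.22). The fibrillar collagen gene Col5a2 was higher (221 ± 49.5 to 673 ± 163 CPM, 1.603 ± 0.21), as was the axon guidance ligand Slit2 (0.87 ± 0.12). The growth factor genes Vegfd (52.9 ± 13.6 to 14.3 ± 2.22 CPM, -1.88 ± 0.19), Igf1 (-1.17 ± 0.17) and Bmp4 (-0.89 ± 0.19) were lower, together with Etv4 (-1.38 ± 0.26) and Etv5 (-1.28 ± 0.22), transcription factors induced by receptor tyrosine kinase signalling. The inositol phosphatase gene Inpp5a (107 ± 22.2 to 37.4 ± 2.49 CPM, -1.51 ± 0.15) and the inositol kinase gene Itpkb (-0.95 ± 0.19) were lower, and the calcium release channel Itpr3 was higher (1.85 ± 0.34). The defensin Defb1 (3389 ± 1479 to 1135 ± 233 CPM, -1.58 ± 0.29) and the prostaglandin D synthase Ptgds (-1.52 ± 0.21) were lower. Adjusted p-values of these 14 genes lay between 0.00202 and 0.048. Of the 17 alternative settings, Sfrp1, Vegfd and Inpp5a passed in 17, Fzd8, Col5a2, Slit2, Igf1 and Ptgds in 16, Etv5 in 13, Itpr3 and Defb1 in 11, Etv4 in 10, Itpkb in 9 and Bmp4 in 6. The block for the series of the animal number ended the call of 9 of the 14, and leaving out KO replicate 2 that of 8.

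The number of changed genes was compared over the 35 splits of the 8 libraries into 4 and 4. The real split gave 316 and the highest of the others 1, so 1 of 35 splits gave a result as large. That is the fewest that 35 splits allow, so chance is made unlikely for the count but is not excluded. The splits took no account of the series of the animal number, and with a block for it the count was 29. For the number of lists past camera's threshold, 2 of 35 splits gave as many as the real 16, the highest other also giving 16, so chance cannot be excluded for that count. The lowest other gave 4, and splits with 2 libraries of each group on a side gave 5 to 16. Passing camera with the preset correlation therefore does not by itself show a difference by genotype for a list.

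The rise of cell cycle genes is a pattern for which immune cells, 1 library or a technical trend were weighed. The median log2 fold change of the 10 immune markers was 0.0837 against 2.27 for the cell cycle list, but the markers went both ways with an SD of 1.22 (Csf1r 2.21, Cd68 1.96 and Ptprc 1.56 against Fcer1g -1.27 and H2-Ab1 -0.90), so this does not decide for or against immune cells. The share of all counts on the immune list was higher in KO (0.00594% against 0.00313%, exact permutation p = 0.0286). That rise rests largely on Csf1r (7.12 to 32.7 CPM), whose exons overlap Hmgxb3, so the share does not decide either. Without KO replicate 4 the list's mean was 1.51 with 7 members past the threshold, and with length and GC trends removed it was 1.79 with 15, which argues against that library or that trend as the whole cause. With a block for the series of the animal number the mean was 1.77 with 1 member past the threshold. Immune cells, dividing cells within the sorted tubules and another cell type that the lists do not cover all stay open.

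The lower magnesium and calcium transport genes were set against a lower share of distal convoluted tubule cells and against shifts of segment. A lower share would lower Slc12a3 about as much as the 9 called genes, whose log2 fold changes had a median of -2.27, but Slc12a3 stood at -0.406 (SE 0.25), and at -0.72 without KO replicate 1, which argues against a lower share as the whole cause. No p is given for this difference, since the 9 genes were chosen for being lower. A shift towards the late distal convoluted and connecting tubule would raise the principal and connecting tubule list, whose per-library level (mean log2(CPM + 1)) had a KO minus Control difference of -0.716 (SE 0.248), with 11 of its 12 members lower. As a share of all counts the same list was higher in KO (0.176% in KO against 0.141% in Control, exact permutation p = 0.0571), since Tfcp2l1, the member with most counts, was higher (772 to 1247 CPM). The difference in level had an exact permutation p of 0.0571, 0 of the 12 members passed the threshold, and the share went the other way. This comparison therefore does not decide for or against that shift for the magnesium genes. If late-segment cells are rich in calcium genes such as Calb1 and Slc8a1, the shift would raise the calcium list. That list's level went from 8.57 ± 0.198 in Control to 7.66 ± 0.307 in KO (SD, n = 4 each), with 4 of 14 members at a fold change above 0. Its share of all counts was 2.95% in Control and 2.81% in KO. These values argue against the shift for the calcium genes. Fewer late distal convoluted and connecting tubule cells in the KO fragments could lower calcium genes such as Calb1 and Slc8a1 together with the principal and connecting tubule list. The same -0.716 goes in that direction, but the 4 called calcium genes had a median of -2.57, so this explanation stays open for the calcium genes, beside a change of expression within the segment. With a batch term for the form of the file name the magnesium list held 1 higher and 5 lower calls and the calcium list 4 lower. With a block for the series of the animal number the magnesium list held 2 lower calls and the calcium list 0, while the lists' mean log2 fold changes were -0.84 and -0.86, against -0.89 and -0.92 without it. Pvalb, at -8.06 without the block, weighs heavily on the magnesium mean.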
